A study of Mus musculus with 2 samples.

How the data were processed

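Chromatin from the midbrain of mouse embryos (strain B6NCrl, embryonic day 13.5, male and female embryos pooled) was immunoprecipitated with an antibody against H3K27me3, the trimethylated lysine of histone H3 that Polycomb complexes deposit, and sequenced. The series holds 1 group with 2 biological replicates, each made of 2 technical replicates per the labels, with DNA fragments of 300 to 500 bp. No second condition was part of the data used here, so the comparisons made were between the 2 replicates, between parts of the genome and between groups of genes.

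The deposited files were peak lists on the mouse assembly mm10, per the file headers: 1 list per replicate, 1 list of both replicates pooled, and 1 list of replicated peaks. The headers give each replicate's list as derived from that replicate's filtered alignments together with further files whose role they do not state, and these were not the same for both replicates: the list of replicate 1 used both of these further files and that of replicate 2 used 1 of them. The pooled list was derived from both alignments and both further files, and the replicated list from the 3 other lists, per the file headers. The aligner, the peak caller and the rule for calling a peak replicated are not given in the sources used here. Each peak carries a signal value, which the authors computed and deposited and whose scaling is not stated. Each peak also carries the −log10 of a p-value and of a q-value, as deposited by the authors. These values are the peaks' own and were used only to describe, rank or filter peaks. The lowest −log10 p in any list was just above 2.

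The files hold no read counts, so the depth of each library is unknown, no count model was fitted, and no interval for read sampling can be given. A base outside every peak is a base where no peak was called, not a base without the mark. With 1 group of 2 replicates, no test here measures the spread between animals: the values after ± are the SD over the 2 replicates' own lists, and p-values refer to genes or positions in the genome, which are not replicates.

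Overlapping peaks within a list were merged before bases were counted. A peak was counted as shared when at least 50% of its bases lay under peaks of the other list. Chance overlap was measured with 100 circular shifts of the peaks along each chromosome on coordinates without assembly gaps, seed 1, one-sided; the smallest p these can give is 0.0099. Gene positions were taken from GENCODE release M21 and sequence from GRCm38, which is the assembly mm10. Each of 21911 protein-coding gene symbols was given a promoter window, the union of 2 kb on both sides of every annotated transcription start, and was called marked when any replicated peak overlapped that window. This is a low bar for genes with many starts, so the percent of the window under peaks was computed as well, in each replicate's own list. Bases under peaks were assigned to promoter windows, then exons, then introns of any gene, and then to intergenic sequence. The CpG ratio is the number of CpG dinucleotides observed over the number expected from base composition, within 1 kb of the gene's 5′ end. Domains were replicated peaks joined across gaps of up to 3 kb.

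The 24 gene lists, their tests and the rule for the genes named in the text were fixed before the data were examined. Each list's share of marked genes was compared with that of all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 24 lists, and its 95% interval is the exact binomial one, which covers counting of genes only. Several lists share genes with others. The named genes were the 3 marked members of each list with the highest mean coverage of the window and the first 2 unmarked members by name (2 and 1 for lists of many genes), the genes in the 10 longest domains, the genes of the 5 replicated peaks with the highest signal, 15 regional and neuronal genes named in advance, and the 5 genes with the largest difference between replicates. In the text below these are given in part. The alternatives were 1 shared base or a reciprocal overlap of 50%, −log10 q of at least 2 or 5, windows of 1 kb or 5 kb, at least 25% of the window covered, each replicate's list alone, the pooled list, the overlap of the replicates' own lists, joining gaps of 1 kb or 10 kb, 10000 random gene lists matched on CpG ratio in 20 bins, and genes within 100 kb counted as 1 locus. Leaving out the X chromosome, using only the 5′ end of each gene, and the 20000 peaks of lowest p for the X chromosome were chosen after seeing the data.

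The scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. They were first tested on simulated data. Shares of overlapping peaks of 20.2%, 41.2% and 80.4% were recovered as 20.3%, 41.2% and 80.4%. For simulated lists of 20 to 45 genes among 21911 genes, a true share of 60% was called in 49 of 54 cases, a share of 50% in 35 of 53 and a share of 10% in 25 of 53. Lists with no difference, of all the sizes in use, were called in 9 of 300 cases. The simulated lists shared no genes and held genes drawn independently, unlike some of the real ones.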

Results

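H3K27me3, the histone mark of Polycomb repression, was mapped in midbrain tissue of mouse embryos at embryonic day 13.5, an age at which dividing progenitors and young neurons are both present. The midbrain group comprised 2 biological replicates, each from pooled male and female embryos. Replicate 1 held 128106 peaks covering 51.4 Mb and replicate 2 held 110723 peaks covering 53.4 Mb, with median lengths of 239 bp and 277 bp. The authors' list of replicated peaks held 61592 peaks with a median length of 471 bp and covered 50.5 Mb, or 1.91% of the genome. Read depth is unknown, as the lists carry no counts. Unless stated otherwise, marked genes and domains refer to the replicated list, and coverage of a promoter window is the mean ± SD of the 2 replicates' own lists (n = 2).

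The question a single-tissue map addresses is which genes carry the mark. Promoter windows of 6296 of 21911 protein-coding genes (28.7%) overlapped a replicated peak, against a mean of 9.68% and a maximum of 11% over circular shifts (permutation p = 0.0099, the smallest they can give). In the replicates' own lists 7840 and 7282 genes were marked, a mean of 7561 ± 395 (SD, n = 2), and 6424 genes were marked in both. With at least 25% of the window required to be under replicated peaks, 2907 genes were marked. Of the bases under replicated peaks, 27.9% lay in promoter windows, 3.96 times the mean of the shifts, whereas intergenic sequence held 35.0% (0.682 times). Introns held 32.0% (0.838 times), a depletion that did not pass with promoter windows of 1 kb (0.962 times, permutation p = 0.119). Marked promoters were least common among genes with few CpG dinucleotides: 12.8% of the group with the lowest CpG ratios were marked, 40.6% of the middle group and 32.9% of the group with the highest, the 3 groups being of equal size. The highest group exceeded the lowest by 20.1 percentage points (Fisher's exact test, two-sided, p = 2.05e-188, genes as units), and by 19 and 17.2 points in the lists of replicates 2 and 1.

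All 39 genes of the Hox clusters, which pattern the hindbrain, spinal cord and trunk, had marked promoters in both replicates' lists (100%, exact 95% interval from 91%; adjusted exact p = 5.55e-21, Fisher's exact test). The median Hox promoter window was 99.6% ± 0.6 covered (SD, n = 2). The Hox genes lie in 4 loci that each held a long domain, so the 39 genes are not independent. The HoxC domain, on chromosome 15 from 102894778 to 103105116 (mm10), spanned 210 kb and 9 protein-coding genes from Hoxc13 to Hoxc4. The HoxA domain spanned 194 kb on chromosome 6 from 52139219 to 52333042 and ran past Hoxa13 to include Evx1, a neighbouring homeobox gene. The HoxB domain, on chromosome 11 from 96228422 to 96382994, spanned 155 kb and held Hoxb9 to Hoxb1 but not Hoxb13. The HoxD domain spanned 134 kb on chromosome 2 from 74639334 to 74773437, with Evx2 at its end. Peaks covered 91.6% ± 0.6, 90.0% ± 1.5, 89.4% ± 1.6 and 91.6% ± 1.1 of these 4 domains (SD, n = 2).

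**Figure D1:**
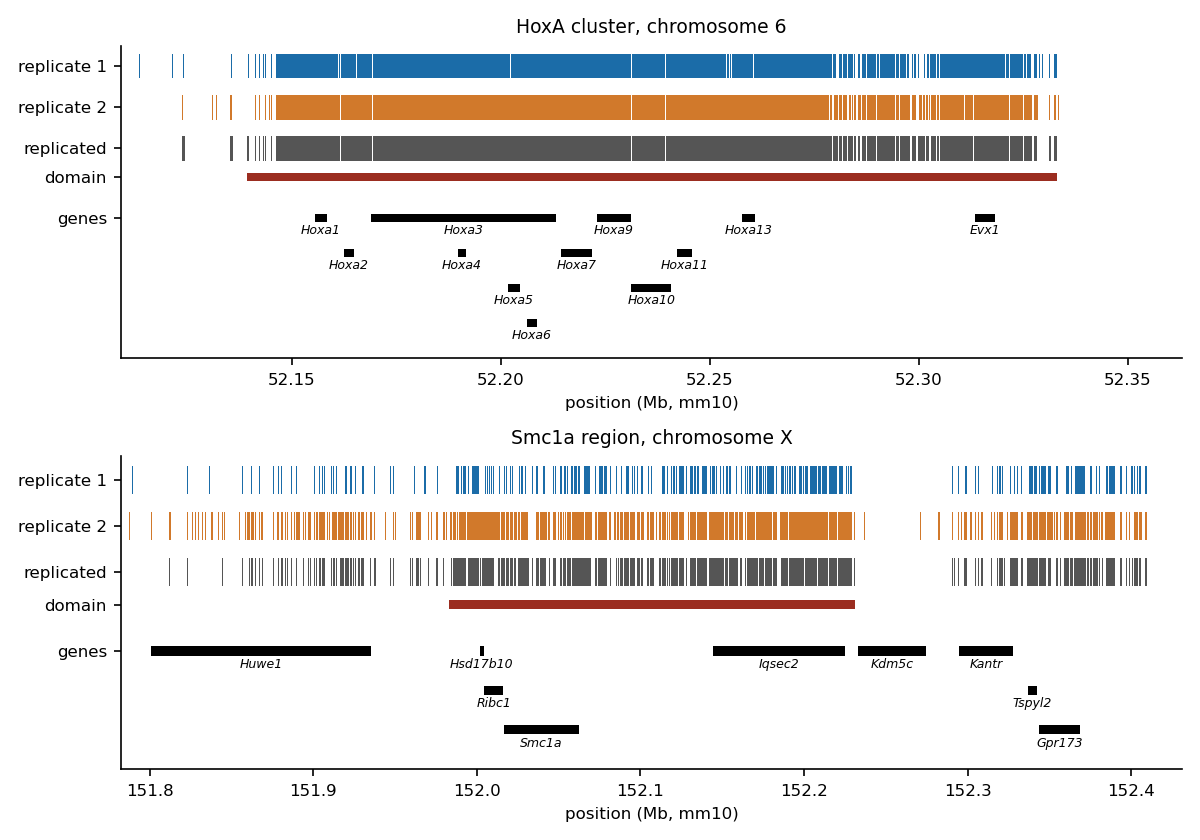
H3K27me3 peaks in each replicate's own list and in the replicated list, the joined domain and protein-coding genes (predicted genes without a name left out) over the HoxA cluster and over the longest domain, on the X chromosome; the horizontal axes are positions in Mb on mm10. The HoxA domain of 194 kb was covered to 90.0% ± 1.5 (SD, n = 2), whereas the X domain of 248 kb was covered to 45.7% in replicate 1 and 77.9% in replicate 2 and ended 1.98 kb before Kdm5c.

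Replicated peaks joined into 19513 domains covering 80.2 Mb, of which 1848 reached 10 kb, 118 reached 50 kb and 18 reached 100 kb. The counts depended on the gap and on the list: 5 reached 100 kb with a gap of 1 kb, 106 with 10 kb, and 41 in the list of replicate 2 alone. With the X chromosome left out, 10 reached 100 kb. Besides the Hox clusters, the 10 longest included 3 other autosomal domains. A domain of 160 kb on chromosome 7 from 49612194 to 49772425 held Dbx1, a homeobox gene of spinal interneuron progenitors, and Htatip2; 85.9% of its bases were intergenic. Sox1, a transcription factor of neural progenitors, lay in a domain of 146 kb on chromosome 8 from 12289948 to 12435681. Casz1, a zinc finger transcription factor, lay in a domain of 124 kb on chromosome 4 from 148832202 to 148955913, and 80.5% of that domain was intronic. The remaining 3 of the 10 lay on the X chromosome and are described with it. The replicated peak with the highest signal in the authors' list, 17.5, spanned 30955459 to 30959871 on chromosome 6 over an exon of Klf14, and the next highest (14.7) lay over Neurog3, a determinant of endocrine cells, on chromosome 10 from 62126352 to 62139876. Peaks 3 and 4 were both in the HoxD cluster (14.6 and 14.4), and the fifth covered an exon of Egr3 on chromosome 14 (13.7).

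Genes that pattern the midbrain itself carried the mark, as did those of other brain regions. All 32 midbrain and isthmus regulators were marked (adjusted exact p = 1.76e-17), as were 29 of 30 forebrain regulators (adjusted exact p = 1.22e-14) and all 31 hindbrain and spinal cord regulators (adjusted exact p = 5.28e-17, each by Fisher's exact test, with the same counts in both replicates' lists). Within the midbrain list, windows of Wnt1, a signal of the midbrain-hindbrain boundary, Helt and Nkx6-2 were covered completely (100%) in both replicates. Windows of Gata2 and Pax7, regulators of GABAergic neurons and of dorsal midbrain, were covered to 96.7% ± 1.7 and 93.0% ± 2.7 (SD, n = 2). The engrailed genes En1 and En2 had 63.3% ± 7.5 and 70.5% ± 7.5 of their windows covered, and Otx2, which is required for fore- and midbrain identity, had 28.0% ± 8.0. Among forebrain regulators, Six3 and Gbx1 were covered completely and Gsx2 to 99.8% ± 0.3; Foxg1, a telencephalic transcription factor, had 81.7% ± 13.4. Neurod6, a gene of forebrain projection neurons, was the unmarked member, with no peak in either replicate. Olig1, Olig2 and Prdm13 had completely covered windows in the hindbrain and spinal cord list.

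**Figure D2:**
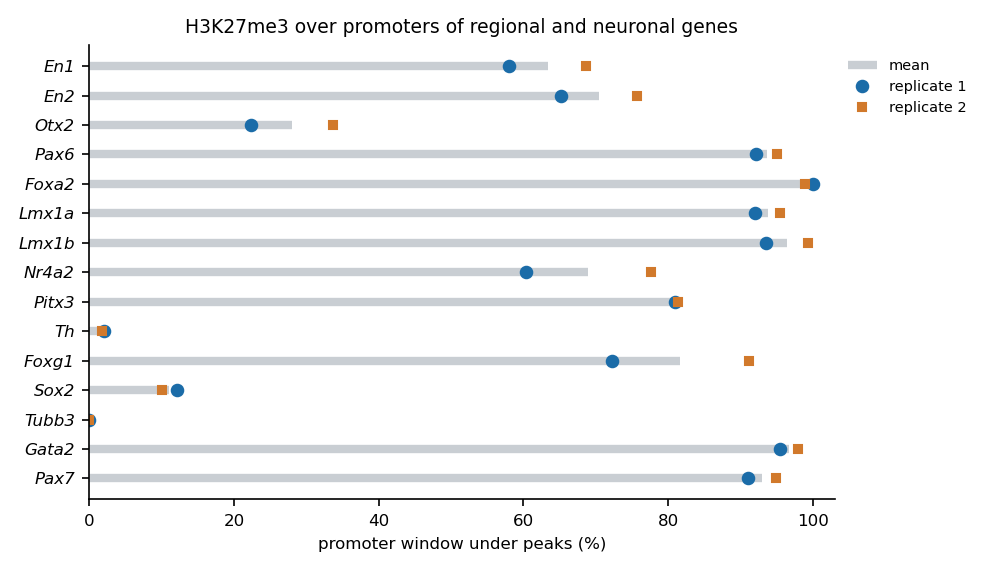
Percent of the promoter window under H3K27me3 peaks (horizontal axis) for the 15 genes named in advance; bars are the mean of the 2 replicates, circles replicate 1 and squares replicate 2. Th, Sox2 and Tubb3 were not marked in the replicated list, and Otx2 had the lowest mean among the marked genes, 28.0%.

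Of 25 genes of the dopaminergic lineage, 22 were marked (88.0%, adjusted exact p = 2.08e-09, Fisher's exact test), and 24 were in each replicate's own list. Windows of the transcription factors Foxa2 (99.5% ± 0.8), Lmx1b (96.4% ± 4.1), Lmx1a (93.7% ± 2.5), Pitx3 (81.1% ± 0.2) and Nr4a2 (68.9% ± 12.2) were covered over most of their length (SD, n = 2). Slc6a3, the dopamine transporter, was covered to 99.3% ± 1.1 and Ret, a receptor for glial-derived factors, to 97.0% ± 4.2. The 3 unmarked members were enzymes of dopamine or retinoid metabolism. All 3 also had low CpG ratios (Th 0.159, Ddc 0.239, Aldh1a1 0.185). By this measure they fall in the group with the lowest CpG ratios, of which only 12.8% of genes were marked. The ratio was taken at the gene's 5′ end alone. Their windows, of 11415, 24145 and 8047 bp, also cover other starts, where it was not measured. Their lack of the mark can therefore be tied neither to function nor to CpG content. Th, the rate-limiting enzyme of dopamine synthesis, had 1.87% ± 0.12 of its window under peaks, Ddc had 1.94% ± 0.83, and Aldh1a1 had no peak in either replicate.

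Regulators of lineages that do not form midbrain were also marked. These were 35 of 40 mesoderm and muscle regulators (adjusted exact p = 3.56e-14), 23 of 26 endoderm regulators (adjusted exact p = 7.35e-10) and 22 of 26 surface ectoderm and neural crest regulators (adjusted exact p = 9.09e-09, all by Fisher's exact test). Pax9, Foxf1 and Barx1 in the mesoderm list, Cdx2, Onecut3 and Mnx1 in the endoderm list, and Hmx1 and Dlx4 in the ectoderm list had completely covered windows. Exceptions without a peak in either replicate included Myf5, a muscle determination factor, Hnf4g, Foxi1 and the keratin gene Krt14. Foxi1 and Krt14 had CpG ratios of 0.254 and 0.231, in the group with the lowest ratios, of which 12.8% of genes were marked. Myf5 and Hnf4g, at 0.376 and 0.340, were in the middle group. Of unmarked genes named from other lists, Neurod6, Fabp7, Dcx, Cdh5 and Col3a1 also had ratios in the lowest group. Dll1, Tubb3 and Actb did not. Across the families of developmental transcription factors fixed as a list, among them Fox, Sox, Pax, Tbx, Lhx, Nkx, Gata and Dlx, 117 of 136 genes were marked (86.0%, adjusted exact p = 3.40e-43); 73 of the 136 belong to other lists as well. Among Wnt, Fgf, Bmp and Hedgehog ligands 55 of 65 were marked (84.6%, adjusted exact p = 5.51e-20), with Wnt1 and Wnt10b covered completely and Bmp10 without a peak in either replicate.

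Of 30 genes used in neural progenitors 17 were marked, above the share of other genes (56.7%, adjusted exact p = 0.00234, Fisher's exact test). Windows were covered to 93.6% ± 2.1 at Pax6, 52.2% ± 19.9 at Hmga2 and 48.0% ± 3.9 at Hes1 (SD, n = 2). Dll1 and Fabp7, a Notch ligand and a radial glia marker, had no peak in either replicate, and Sox2 had 11.02% ± 1.45 of its window under peaks of the replicates' own lists without a replicated peak. Of the 30 pan-neuronal genes 12 were marked, which did not differ detectably from other genes (difference 11.3 points, adjusted exact p = 0.224). Ina, Cplx1 and Nefl, which encode a neurofilament-associated protein, a synaptic protein and the light neurofilament, had windows covered to 79.2% ± 0.3, 71.1% ± 1.1 and 65.9% ± 1.6, whereas the neuronal tubulin gene Tubb3 had no peak in either replicate and Dcx had 2.42% ± 3.42. Transmitter receptors and channels were marked at 85 genes of the list (69.1%, adjusted exact p = 8.64e-20, Fisher's exact test), with 83.7% and 72.4% in the lists of replicates 1 and 2. The median window of that list was 20.2% ± 0.04 covered, whereas Kcnc4 and Adra1d were covered completely.

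Several lists were marked less often than other genes, among them ubiquitously used genes. Ribosomal protein genes had 9 of 84 marked (10.7%, adjusted exact p = 0.000159, Fisher's exact test), and Rpl3l, a muscle form, had the highest coverage in this list at 16.5% ± 2.3 (SD, n = 2). Housekeeping genes had 3 of 30 marked (adjusted exact p = 0.0296), namely Reep5 (14.1% ± 5.3), Psmb2 (10.7% ± 8.9) and Rab7 (0.921% ± 0.6), and Actb had no peak in either replicate. The housekeeping call was lost in 5 alternative settings, the list of replicate 2 alone (adjusted exact p = 0.0687), the overlap of the replicates' own lists (0.0702), windows of 5 kb (0.0645), −log10 q of at least 5 (0.143) and the 5′ end of the gene alone (0.0695). Olfactory and vomeronasal receptors had the lowest share, 8 of 1418 (0.564%, difference −30.1 points, adjusted exact p = 2.18e-198, Fisher's exact test). These receptor genes lie in 160 loci when those within 100 kb are joined, so they are not independent. Against random lists with the same low CpG ratios, of which 9.75% were marked, the difference was smaller, −9.19 points (adjusted permutation p = 0.00032, from the smallest p the draws can give). Of the zinc finger protein genes 48 of 365 were marked (13.2%, adjusted exact p = 3.29e-12). Liver and gut genes had 2 of 29 marked (6.90%, adjusted exact p = 0.00854), Apoc3 and Apoh, while Afp and Ahsg had no peak in either replicate. That difference was lost with either replicate's list alone (adjusted exact p = 0.0819 and 0.131) and against random lists with the same CpG ratios (adjusted permutation p = 0.12). Clustered protocadherins had 10 of 56 marked (17.9%, adjusted exact p = 0.0875, Fisher's exact test). Against lists matched on CpG ratio, of which 36.9% were marked on average, their share was lower (adjusted permutation p = 0.00452). The 56 genes lie in 2 loci, whereas the matched lists drew single genes, so that p treats neighbouring genes as independent.

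Marker genes of non-neural cells that midbrain tissue holds were described apart. Of endothelial and pericyte genes 16 of 25 were marked (64.0%, adjusted exact p = 0.000392, Fisher's exact test), led by Sox18 (100%), Cldn5 (94.7% ± 4.8) and Sox17 (90.9% ± 3.4), while Cdh5 had 1.11% ± 1.56 of its window under peaks. The median window of the endothelial and pericyte list was 18.4% ± 1.0 covered. Of meningeal and connective tissue genes 16 of 24 were marked (66.7%, adjusted exact p = 0.000205, Fisher's exact test), led by Alx4, Foxc1 (95.1% ± 5.2) and Twist1 (94.6% ± 0.9), and Col3a1 had no peak in either replicate. Here the median window was 26.4% ± 0.4 covered. Blood and immune genes had 13 of 30 marked (43.3%, adjusted exact p = 0.108), with Tal1 at 77.1% ± 6.4 and Runx1 at 54.2% ± 1.3 (SD, n = 2). That difference depended on the setting: the share was higher than in lists with the same low CpG ratios (adjusted permutation p = 0.0118) and passed with the pooled list (adjusted exact p = 0.026), but it lay below that of other genes at −log10 q of at least 5 (difference −2.61 points, adjusted exact p = 0.831). Genes of the Polycomb group were marked at the same count, 13 of 30 (adjusted exact p = 0.108), including Bmi1 (62.8% ± 6.3), Cbx8 (45.1% ± 1.5) and Cbx4 (37.1% ± 1.5), while Eed and Cbx6 had no peak in either replicate. Among cell cycle inhibitors and imprinted genes 15 of 23 were marked (65.2%, adjusted exact p = 0.000426, Fisher's exact test), with a median window covered to 18.4% ± 1.4. Cdkn2a, which encodes inhibitors of the cell cycle, had 96.0% ± 0.7 of its window covered, Phlda2 95.8% ± 6.0 and Dlk1 92.2% ± 9.3, and Cdkn1c was unmarked at 7.40% ± 1.84.

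**Figure D3:**
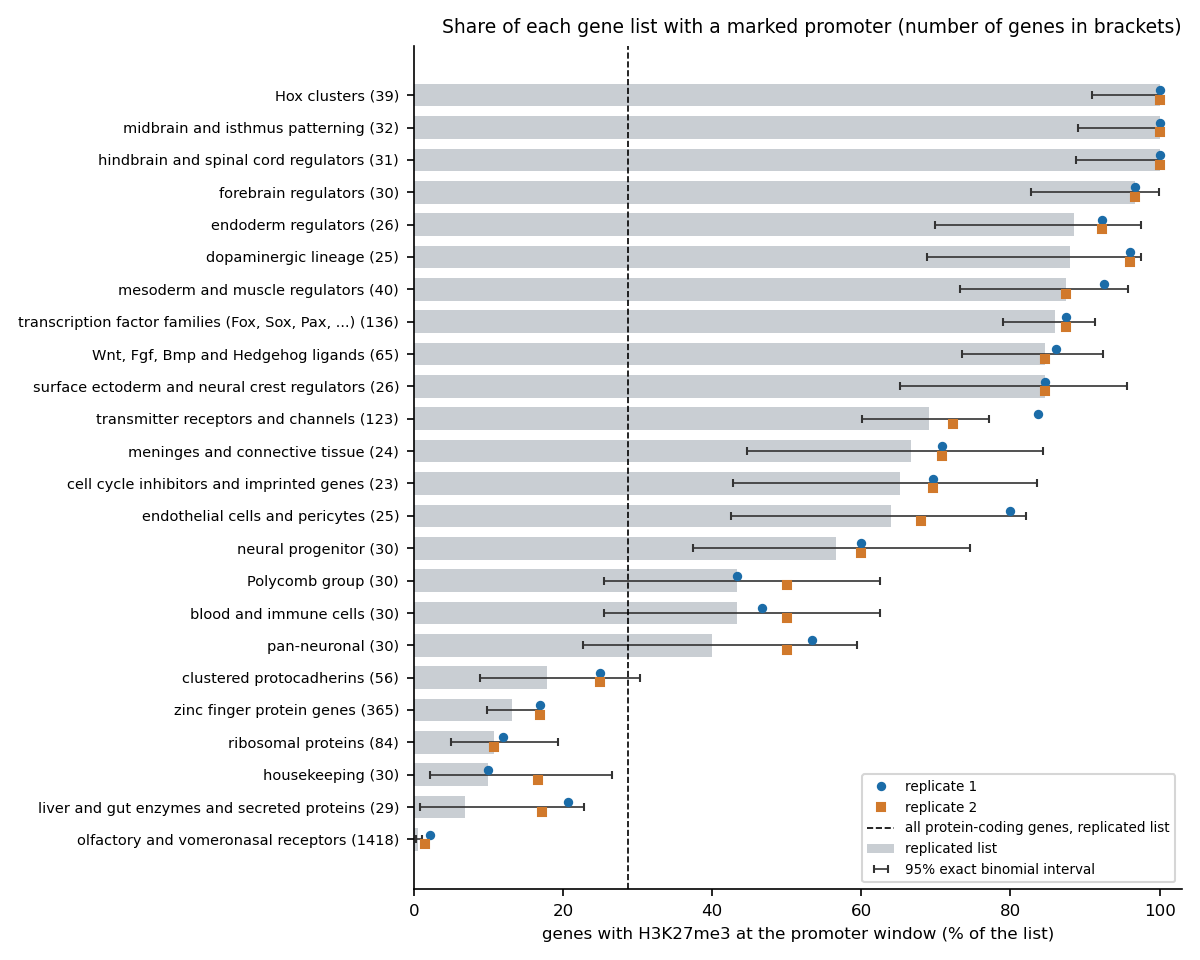
Percent of the genes of each of the 24 lists with a marked promoter window (horizontal axis; list sizes in brackets): bars are the replicated list with exact 95% binomial intervals, circles and squares the lists of replicates 1 and 2, and the dashed line the 28.7% of all protein-coding genes. Hox, midbrain and hindbrain regulators were at 100%, and olfactory and vomeronasal receptors at 0.564%.

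The replicates were compared by the overlap of their own lists. Of replicate 1's peaks 40.04% had at least 50% of their bases under peaks of replicate 2, and 38.9% held the other way, against means of 2.17% and 1.93% for shifted peaks (permutation p = 0.0099 for both, the smallest that the shifts can give). With reciprocal overlap required these shares were 23.2% and 26.9%, and among peaks with −log10 q of at least 5 they were 61.8% and 53.7%. The bases under both lists were 40.7% of those under either, 30.3 Mb. Sharing followed the strength of the peaks: 99.6% and 98.4% of the 5000 peaks of lowest p in replicates 1 and 2 were shared, but 26.3% and 25.2% of the peaks ranked beyond 50000. All 61592 replicated peaks were entries of the pooled list, of which they made up 47.5% of the peaks and 75.5% of the bases. Both replicates covered at least 50% of 58.6% of the replicated peaks, and a single shared base sufficed for 79.0%. Across 48676 replicated peaks that met a peak in each replicate, the 2 signal values had a Pearson r of 0.63 and a Spearman rho of 0.45, and peaks are not independent replicates.

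The chromosomes differed in how much of them was covered, and the X chromosome differed between the replicates. Chromosome 19 held 1.965 times and chromosome 11 held 1.61 times its share of the genome in replicated peak bases, and chromosome 3 held 0.586 times. On the autosomes, the ratio of covered bases in replicate 2 to replicate 1 lay between 0.912 (chromosome 12) and 0.961 (chromosome 10). Promoter windows could go the other way. Of the marked genes named in advance, all on autosomes, only Foxa2 was lower in replicate 2 (100% and 98.9%). The others were higher, among them Foxg1 (72.2% and 91.2%) and Pitx3 (81.0% and 81.3%). The X chromosome had 9219 peaks over 2.70 Mb in replicate 1 and 18934 peaks over 7.73 Mb in replicate 2, a ratio of bases of 2.86. The authors' signal, whose scaling is not stated, was compared at replicated peaks met in both lists. Its median log2 difference, replicate 2 minus replicate 1, was 0.23 at 6016 X peaks and 0.019 at 42660 autosomal peaks. Stretches called in replicate 2 alone are left out, so these values cannot be set against the ratio of bases. The X share of all peak bases was 5.26% and 14.5% in the 2 replicates, a mean of 9.87% ± 6.51 (SD, n = 2), and with 2 replicates of 1 group no test of this difference between animals was possible. Without the X chromosome, the overlap of bases between the replicates was 42.9%; on the X alone, 72.0% of replicate 1's peaks were shared with replicate 2, but 17.8% of replicate 2's peaks with replicate 1.

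**Figure D4:**
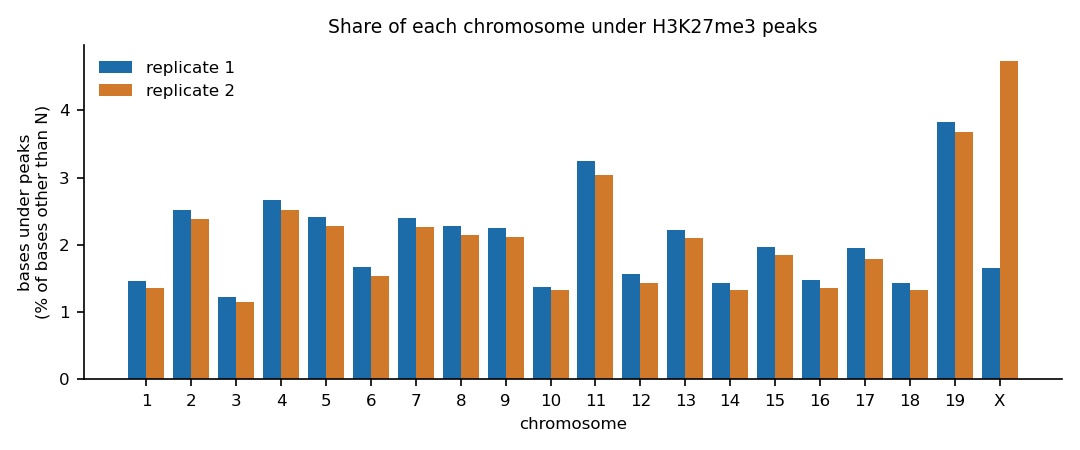
Bases under H3K27me3 peaks as a percent of the bases other than N of each chromosome (vertical axis) in replicates 1 and 2. On every autosome replicate 2 was slightly below replicate 1, with ratios from 0.912 to 0.961, and on the X chromosome the ratio was 2.86.

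The longest domain of all lay on the X chromosome from 151982805 to 152231041, spanned 248 kb and held Hsd17b10, Ribc1, Smc1a, which encodes a cohesin subunit, and Iqsec2. Peaks covered 45.7% of it in replicate 1 and 77.9% in replicate 2. The longest domain anywhere in the genome was 407 kb in the list of replicate 2 alone and 213 kb in that of replicate 1. With gaps of 1 kb and 10 kb it was 183 kb and 543 kb. The locus was not recorded for these settings, so these lengths need not belong to the domain on the X. A domain of 158 kb from 103294331 to 103452159 held Cdx4, Chic1 and Tsx, overlapped the antisense gene Tsix and ended 8.21 kb before Xist, the RNA that silences 1 X chromosome in female cells. It was covered to 34.2% and 64.9%. A domain of 137 kb from 99476499 to 99613154 contained no annotated gene, lay 5.22 kb from Pja1, and was covered to 41.9% and 74.8%. The 5 genes whose promoter windows differed most between the replicates were all on the X and all higher in replicate 2: Apoo (31.2% and 90.1%), Nhs (16.2% and 74.99%), Grpr (15.2% and 73.4%), Zfx (26.9% and 82.4%) and Zdhhc15 (9.80% and 63.7%). Of the 100 genes with the largest differences 83 were on the X, all higher in replicate 2. On the X chromosome 241 of 948 genes (25.4%) were marked in replicate 1 and 308 (32.5%) in replicate 2. The autosomal share was higher in each replicate, 36.2% and 33.3%. Each gene list's side of the threshold was the same with the X chromosome left out.

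**Figure D5:**
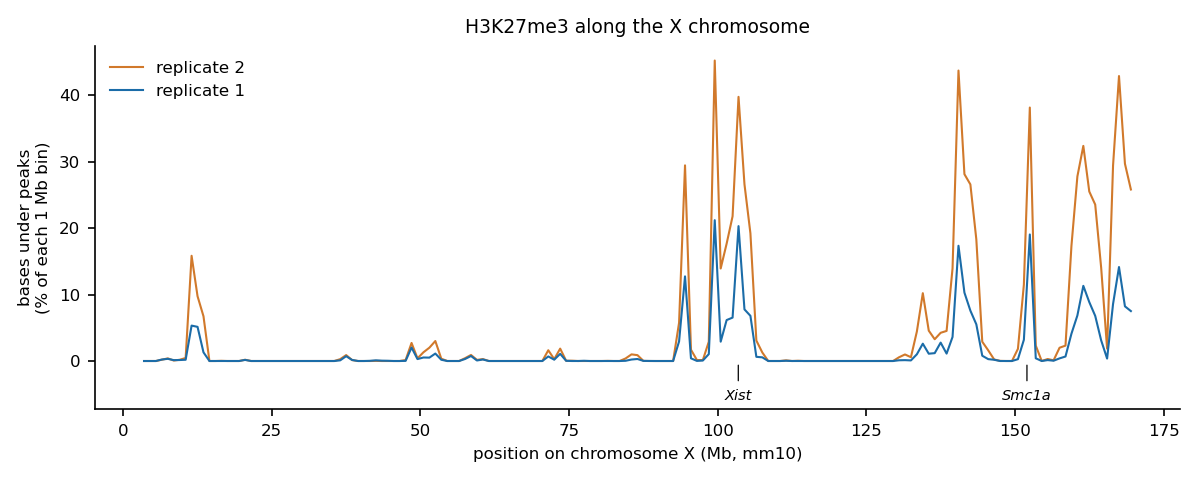
Bases under H3K27me3 peaks as a percent of each 1 Mb bin (vertical axis) along the X chromosome (horizontal axis, Mb, mm10) in replicates 1 and 2; lines mark Xist and Smc1a. Both replicates had their peaks in the same stretches, and the highest bin reached 45.2% in replicate 2 and 21.2% in replicate 1.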

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

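Leaving out the X chromosome, the use of the 5′ end of each gene alone and, for the X share, the 20000 peaks of lowest p were chosen after seeing the data. Of all values recomputed, 348 kept their direction and their side of the threshold, moved by less than the replicate spread or, for counts, stayed within 1.5 times, while 18 moved further, 12 no longer passed, 3 newly passed and 6 changed direction. Some of the 348 were kept by construction. The overlap of bases ignores the rule for shared peaks, and each replicate's X share was judged by the SD of both. Replicate 1's peak overlap, 40.04%, ranged from 23.2% to 61.8% across settings, above the shifts each time. The share of replicated peaks covered by both replicates, 58.6%, was 79.0% with 1 shared base, 43.2% with reciprocal overlap, and 39.1% and 23.9% with −log10 q of at least 2 and 5, which leaves fewer replicate peaks to overlap. Spearman's rho of the signal, 0.453, was 0.488 on −log10 p, and 0.495 and 0.580 at −log10 q of at least 2 and 5. The X share of peaks in replicate 2 over that in replicate 1, 2.38, rose to 4.01 at −log10 q of at least 5 and 4.53 among the top 20000 peaks; the cause was not tested further than below. Marked genes fell to 2907 with at least 25% of the window covered, by construction. Differences then shrank, as for CpG groups (9.90) and neural progenitor genes (16.8), or grew, as for Hox genes (86.9), these still past the threshold. Domains numbered 30221 with a gap of 1 kb, 13005 with 10 kb, 11938 at −log10 q of at least 5, and 32342 to 43253 with 1 replicate's list alone, which is not filtered for replication; those of at least 10 kb numbered 893, 3010 and 1122 at these first 3 settings. Domains of at least 50 kb numbered 31, 334 and 60 there, and 185 and 137 with the list of replicate 2 or 1 alone; those of at least 100 kb numbered 5, 106 and 9, then 41 and 20, and 10 without the X.

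Housekeeping genes were below other genes by 18.8 percentage points (−18.8). The difference missed the threshold with the list of replicate 2 alone (−16.6 and −25.8 over the 2 lists), in the overlap of the replicates' own lists (−16.2), with windows of 5 kb (−16.8), at −log10 q of at least 5 (−12.6) and at the 5′ end alone (−15.7); the cause was not tested. Liver and gut genes (−21.9) missed it with each replicate's list alone (−16.0 and −15.1) and against lists matched on CpG ratio (−12.6), whose own share is low. Blood and immune genes (14.6) passed it with the pooled list (20.5) and against matched lists (21.7), but turned to −2.61 at −log10 q of at least 5, where the cause was not tested; protocadherins (−10.9) passed it against matched lists (−19.1). With neighbouring genes within 100 kb counted as 1 locus, Hox genes (42.1), endothelial (4.70), meningeal (11.8) and cell cycle and imprinted genes (8.85) no longer passed, and neural progenitor genes turned to −1.24. Pan-neuronal (11.3), blood and immune (14.6), Polycomb group (14.6) and protocadherin genes (−10.9), which did not pass in the main test, turned to −16.5, −9.86, −17.1 and 42.1, again without passing. Most list loci stayed nearly single genes (neural progenitor 17 of 30 marked both ways), but other genes joined into larger loci, 57.9% marked. By construction this lowers such lists' differences, so their losses and turns, and passes of lists below other genes, counted as kept (housekeeping −47.9), decide nothing. All 4 Hox loci and both protocadherin loci were marked, too few to pass at that background. No paired analysis was possible because the series has 1 group. Depth limits every unmarked call, since its size is unknown.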

Other observations

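The count of X stretches, the ratios of mean coverage and the X gene comparisons with genes left out were chosen only after the result was seen. Called H3K27me3 peaks on the X chromosome were concentrated in a small part of it. Of 167 bins of 1 Mb, 30 had at least 5% of their bases under peaks in replicate 2. These 30 bins formed 8 stretches, made up 18.2% of the X and held 90.9% of the X peak bases of replicate 1 and 91.1% of those of replicate 2, with 24.8% of the X's protein-coding gene starts. The stretches included 99 to 106 Mb, which holds the Xist locus and was covered to 10.2% in replicate 1 and 26.3% in replicate 2, 139 to 144 Mb (8.83% and 26.1%), 151 to 153 Mb around Smc1a (11.1% and 24.8%), 159 to 165 Mb (6.84% and 23.4%) and 166 to 170 Mb (9.62% and 32.0%). The ratio of covered bases between replicates lay between 2.23 and 3.91 in the 8 stretches. These ratios and the 91.1% rest partly on the values of replicate 2 by which the bins were chosen. No autosome was divided in the same way. At the edge of the longest domain the mark stopped close to a gene known to escape X inactivation: the body of Kdm5c, 1.98 kb beyond the domain, had 0.429% and 1.98% of its bases under peaks in replicates 1 and 2, whereas the body of Smc1a had 33.2% and 67.2%. Xist, Ddx3x and Kdm6a, also listed as escape genes, had no peak over their bodies in either replicate. Pbdc1, from the same list, had 5.65% and 19.3%. Hprt, G6pdx and Stag2, which are subject to inactivation, also had none. Smc1a, Kdm5c and the stretches are named here after their values were seen.

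The X chromosome excess of replicate 2 was weighed against 3 explanations. Longer or looser peak lists would bring the X shares together among equal numbers of strong peaks, but with the 20000 peaks of lowest p in each list the X share of replicate 2 was 4.53 times that of replicate 1, which argues against them. An even change of X signal may come from X copy number or from the further files used to make the lists. These files were not the same for both replicates. More inactive X chromatin in replicate 2 could come from a larger part of female embryos in its pool. A larger female part would raise X copy number as well, so these 2 explanations are not exclusive. Gains in coverage of gene bodies did not separate them: 8 escape genes gained 2.16 percentage points and 20 genes subject to inactivation 5.96 (difference −3.80, exact permutation test, two-sided, p = 0.536), but an even change scales with the starting level, which was 0.894% and 4.13%, and as ratios of the means the sets rose 3.42 and 2.44 times, so a difference in points does not decide; 3 subject genes within 100 kb of the longest domain (Huwe1, Hsd17b10 and Smc1a) carried most of the gain, 10 of the 20 had no peak in either replicate, and without those 3 the difference was 1.19 (exact p = 0.46). Pbdc1 carried most of the escape genes' gain, and without it as well the difference was −0.454 (exact p = 0.567). The 20 subject genes gained 5.94 points more than 28 autosomal housekeeping genes (permutation test, two-sided, p = 0.00012), and 0.951 points more without those 3 (permutation p = 0.00206), but 27 of those 28 had no peak in either replicate, so any gain on the X gives this outcome and it restates the excess. Both explanations stay open.

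Midbrain regulators are used in parts of the tissue and forebrain regulators largely are not, so partial use could leave less of the midbrain windows covered. The 32 midbrain and isthmus regulators had 75.6% of their windows covered on average and the 30 forebrain regulators 80.6%, a difference of −5.07 percentage points (permutation test over genes, two-sided, p = 0.457; 95% bootstrap interval −17.7 to 8.47). After the linear trend on CpG ratio was removed the difference was −5.54 (permutation p = 0.412), so there was no clear difference for CpG content to account for. Windows covered to less than 50% numbered 9 among the 32 midbrain and isthmus regulators and 3 among the 30 forebrain regulators, a split that was not tested. The prediction had taken a p above the threshold as a negative outcome. However, the bootstrap interval of the mean difference includes both no difference and a sizeable one, so partial use is left open by these lists.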
